A study of Mus musculus with 2 samples.

How the data were processed

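Chromatin accessibility was measured in single cells of wild-type mouse retina at the embryonic stage E14.5 with the droplet-based assay for transposase-accessible chromatin of 10x Genomics. The labels give 2 replicate libraries of 1 group and no other condition, so no groups of samples were compared. The labels do not say whether the replicates came from separate animals or litters. Every SD below therefore measures only the spread between these 2 libraries, which may be technical. Every p-value and standard error (SE) measures how differences between clusters vary between the same 2 libraries. A shift between the libraries that all clusters share is taken out by the main model.

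The values are raw counts: per the file headers, each library has a whole-number matrix of 579 transcription factor motifs by cell barcode, written by software version 1.1.0, and the submitters' processing notes name Cell Ranger and the mouse build mm10. In matrices of this kind a transposase cut inside a peak is counted for every motif found in that peak. A motif count is thus the accessibility of all peaks holding the sequence pattern, not binding by the factor, and factors with like patterns share counts. In the kept cells, 59 motifs, in 23 groups, had exactly the same counts as at least 1 other motif. The settings of the peak calling and of the motif search are not given in the sources used here. Peak positions and gene annotation were not used here, so no coordinates are reported.

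The totals of the barcodes fell into a deep and a shallow group. The filter written before the data were examined kept barcodes from 0.25 to 4 times the median total of their library. It kept 1213 barcodes of replicate 1 and 1246 of replicate 2, but only 0 and 3 of these were in the deep group, because most barcodes are shallow. It was replaced, after the totals had been seen, by a minimum of 300000 motif counts, with the shallower copy of any barcode found in both libraries left out. This kept 890 of 2422 barcodes (36.7%) and 98.3% of the counts of replicate 1, and 1051 of 3033 barcodes (34.7%) and 97.3% of the counts of replicate 2. Results with the first filter are given as an alternative. No doublet caller was run; leaving out the deepest cells was an alternative setting.

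Counts were expressed as shares of a cell's or library's total. Variability of a motif was the coefficient of variation (CV) of depth-scaled counts across the cells of a library in excess of counting noise, and its residual from a smooth trend of log2 CV on the mean. For clustering, log2(counts per 10000 + pseudocount of 1) had the log10 cell total regressed out and was scaled within each library. The first 15 principal components, 20 nearest neighbours and Leiden clustering at resolution 0.5 followed (scanpy 1.11.5, igraph 0.11.9). A first look at the data used another implementation of Leiden, leidenalg, which is among the alternatives. A cluster was called "like" a cell class where at least 3 of its 10 motifs of highest fold were in that class's list, and more than in any other. The 15 motif lists were fixed before the data were examined; this naming rule was set after a first clustering.

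Counts summed per library and cluster (at least 20 cells in each library) were tested with edgeR 4.0.16 (R 4.3.3) using the quasi-likelihood F test, TMM scaling and the library as a block. Each cluster was set against the mean of the others, with Benjamini-Hochberg adjustment over the 579 motifs and a threshold of 0.05. A cluster far from the rest for a motif thus moves the folds of all others the other way. The fit had 5 residual degrees of freedom. The clusters came from the same counts, so these tests name what defines a cluster and are no independent evidence. For a measurement apart from the clustering, each list was held out: cells were clustered again without the list and without motifs correlated with it above 0.7 in both libraries. The clusters highest and lowest for the list were chosen in 1 library and the difference in mean log2 share was measured in the other, in both directions. List members were tested across all such clusters with the same edgeR model. Every motif's shares were also shuffled among the cells of a library, 5 times; this breaks all covariation, also that of motifs in the same peaks, and so only sets the floor of the method. For reference, chosen after the data had been seen, 100 random lists per list were drawn, each member replaced by 1 of the 20 motifs nearest in mean count outside the list, and held out in the same way. List scores were also correlated across cells within each library, with no p-value, since cells are not replicates.

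On simulated data, a CV of 5% was recovered as 5.66% and a CV of 40% as 40.0% in replicate 1. Of 100 motifs changed by 1.05-fold in cluster 4, edgeR recovered 86, of 100 changed by 1.2-fold it recovered 97, and it called 9 of 379 unchanged motifs. In that simulation motifs were drawn independently, clusters were fixed beforehand and motif shares did not differ between the libraries. Its share of false calls cannot be carried over to the real clusters, which were built from the same counts. A simulated difference of 0.29 (log2) in the held-out ganglion cell list came back as 0.30. Because shares add to a fixed total, a list left alone in that simulation had a log2 difference of 0.064 in its share, recovered as 0.061, so small held-out differences can follow from changes in other motifs.

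Named motifs followed a rule fixed with the lists: the 10 of highest share, the 12 most and 6 least variable, the 6 highest and 6 lowest folds past the threshold with the same sign in both libraries for the 3 largest clusters (3 and 3 for others), up to 4 members per list plus all ganglion cell and neurogenic members, and the 3 largest library differences each way. A few motifs that the rule takes are not reported here. Motifs outside it are said to be chosen after their values were seen. Alternatives were DESeq2 1.42.0 in place of edgeR, no TMM, no replicate block, a low-count filter, a fold limit, cells thinned to 1000000 counts (810 and 911 cells deep enough), other cell filters, resolutions and components, the promoter list regressed out, and each replicate left out. Intervals on shares of cells are Wilson 95% intervals and cover counting error only.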

Results

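The data were 2 replicate single-cell accessibility libraries of whole wild-type mouse retina at the embryonic stage E14.5, when dividing progenitors are giving rise to the first neurons, retinal ganglion cells among them. The series belongs to a study of regulatory DNA in ganglion cell formation. Replicate 1 held 3373212147 motif counts over 2422 barcodes and replicate 2 held 3932721221 over 3033 barcodes. The 890 and 1051 cells kept had a median of 3519151 and 3523871 motif counts. The mean count per cell, averaged over the 2 libraries, ranged from 7.51 for the rarest motif to 115750 for the most frequent. Since a cut counts for every motif in its peak, these totals far exceed the number of cuts. Of all barcodes, 1828 occurred in both libraries; only the deeper copy of each was used, and only where it passed 300000 counts.

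**Figure D1:**
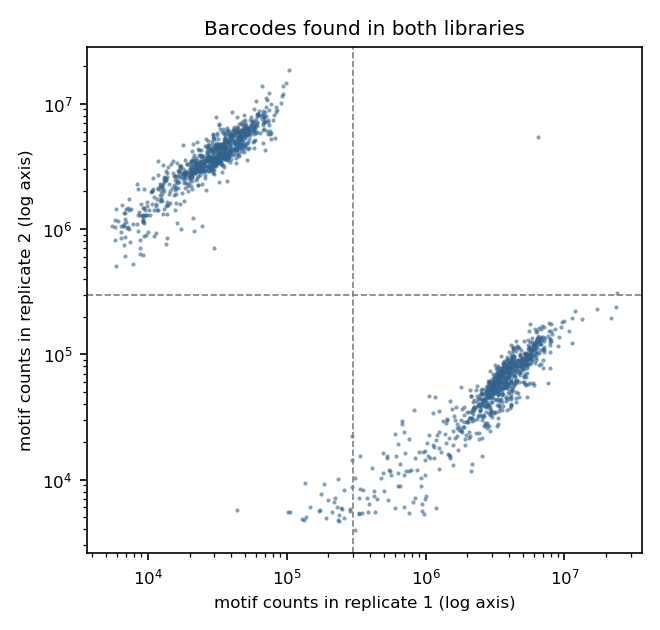
Each point is 1 of 1828 barcodes found in both libraries, placed by its motif counts in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale); dashed lines mark 300000 counts. Only 2 barcodes passed that number in both libraries and 31 in neither.

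The replicates were first compared with each other. The highest shares of counts belonged to short, frequent patterns: MZF1 at 3.14% ± 0.014 (SD, n = 2), ZNF354C at 3.09% ± 0.014 and MAFG::NFE2L1 at 2.56% ± 0.013, followed by Arid3a, Ahr::Arnt, SPIB, ZNF263, MEIS1, SP2 and FOXL1. Together these 10 took 22.9% of counts. Shares across the 579 motifs, which are not independent of each other, had a Pearson r of 0.998 and a Spearman rho of 0.999 between libraries, with a median absolute log2 ratio of 0.021. For 68 motifs the ratio passed 0.1. Lhx8, a LIM homeodomain motif, lay lower in replicate 1 by the widest margin (log2 ratio −1.71), ahead of HOXD12 (−0.75) and RORB (−0.63). In replicate 1 its count equalled that of PAX4 in all 890 cells, and in replicate 2 in 0 of 1051; PAX4 was singled out after its values were seen. HOXC11 (1.19), FOSL1 (0.61) and NFIC (0.43) lay higher in replicate 1. With 1 library on each side these ratios have no test.

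Variability across cells asked which motifs mark differences between cells within the retina. POU4F1, POU4F3 and POU4F2, the motifs of the POU class 4 factors of ganglion cells, had excess CVs of 15.7% ± 0.76, 13.1% ± 0.86 and 11.4% ± 0.22 (SD, n = 2). The median motif had 6.19% in replicate 1 and 6.27% in replicate 2. Above them stood ZBTB7B at 85.9% ± 2.0, HIF1A at 37.4% ± 0.13, ZBTB7C at 37.1% ± 0.11, Stat4 at 26.5% ± 1.1, GLIS2 at 24.1% ± 0.39 and INSM1 at 19.4% ± 1.0. Within the middle of 3 equal classes of cells by depth the excess CV of ZBTB7B was 27.7% and 31.4%, and that of the median motif 4.83% and 4.76%. Zfx, NRF1 and ARNT::HIF1A completed the 12 motifs farthest above the trend. Of the 5 ganglion cell list members 4 lay above the trend in both libraries, with a median residual of 1.04 ± 0.055 on the log2 scale. Of the 12 neurogenic basic helix-loop-helix (bHLH) members 11 did, with a median residual of 0.42 ± 0.077. Of the progenitor lists, SOX motifs had a median of −0.066 ± 0.034, homeodomain motifs 0.22 ± 0.045 and TEAD and NFI motifs 0.11 ± 0.026. GC-rich promoter motifs, a list fixed as a sign of library quality, stood at 0.60 ± 0.0098, with 16 of 20 above the trend in both libraries. Nr2e3 was the least variable for its mean, at 1.16% ± 0.067, before FOXD2, FOXI1, FOXO4, FOXO6 and FOXP3, which share identical counts at 1.24% ± 0.040. Residuals of the libraries had a Spearman rho of 0.918 across motifs. Left to replicate 2 alone, 11 of the 12 most variable motifs stayed among the top 12, and left to replicate 1 alone 8 did.

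**Figure D2:**
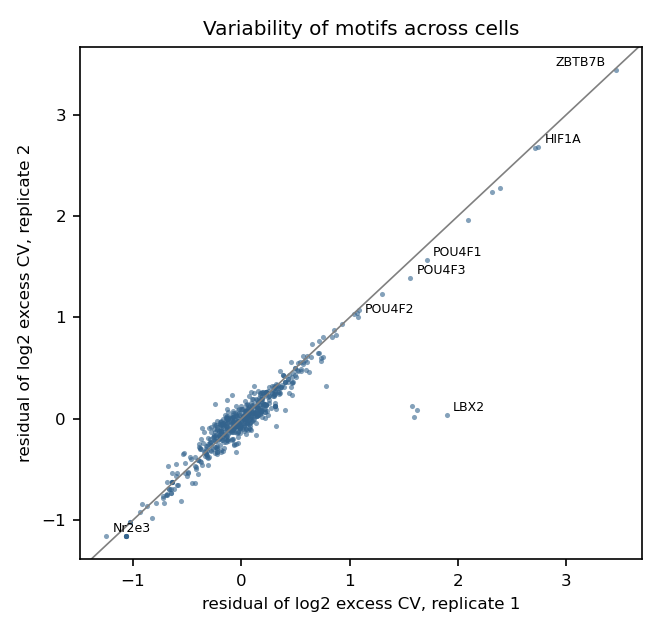
Each point is 1 of 579 motifs, placed by its residual of log2 excess CV from the trend on the mean in replicate 1 (x axis) and replicate 2 (y axis); the line marks equal values. ZBTB7B lies highest in both, POU4F1 stands at 1.71 and 1.57, and LBX2 lies at 1.89 in replicate 1 against 0.040 in replicate 2.

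Clustering of the 1941 cells gave 6 clusters. Replicate 1 clustered alone gave 6 clusters, with an adjusted Rand index, which is 1 for identical clusters, of 0.687 against the joint ones, and replicate 2 alone gave 5, with an index of 0.548. A ganglion cell-like cluster, number 4, held 13.5% ± 0.42 of cells (SD, n = 2), with Wilson 95% intervals of 11.7 to 16.2% in replicate 1 and 11.3 to 15.4% in replicate 2. A neurogenic bHLH-like cluster, number 3, held 14.8% ± 0.71, with intervals of 13.1 to 17.8% and 12.3 to 16.5%. The others stayed unnamed: cluster 1 with 35.3% ± 0.72, cluster 2 with 16.7% ± 0.59, cluster 5 with 13.2% ± 1.4 and cluster 6 with 6.50% ± 0.18 of cells. These shares moved with the resolution: at resolution 0.3 the ganglion cell-like share was 28.3% and no cluster met the rule for the neurogenic name, and at 1.0 the shares were 9.06% and 5.82%. With all deposited barcodes the ganglion cell-like share was 3.44%, and with the cell filter written first neither name was reached.

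The ganglion cell-like cluster was defined by POU class 4 motifs, which are near copies of each other and do not count as 3 independent signs. POU4F1 was higher by a log2 fold of 0.49 ± 0.0087 (SE; edgeR adjusted p = 1.98e-08), POU4F3 by 0.41 ± 0.0067 and POU4F2 by 0.35 ± 0.0094. EBF1 (0.16) and ISL2 (0.046), the other members of the list, passed as well. All 5 members were called, adjusted over all motifs or adjusted over the list alone, and 4 were called with no replicate block. SCRT2 (−0.20) and SCRT1 (−0.19), motifs of zinc-finger repressors, were lower. So was MYBL1 (−1.13 ± 0.055), a motif with only 7.53 counts per cell over all kept cells. Of the 8 E2F motifs, patterns of cell cycle genes, 6 were lower and 0 higher, and 1 was lower with no replicate block. Of the 12 neurogenic motifs 7 were lower and 2 higher (mean −0.028 ± 0.0016, SD, n = 2), and with no replicate block 2 were lower. The mean of the other clusters includes clusters 3 and 6, which were high for neurogenic motifs (0.12 and 0.053). Clusters 1 and 2 stood lower than cluster 4 (−0.069 and −0.055), and cluster 5 stood at −0.019. Of the 7 TEAD and NFI motifs of progenitors 4 were lower, with TEAD1 at −0.058 and TEAD4 at −0.046. Of lists for other cell classes, 10 of 13 horizontal and amacrine motifs were higher and 0 lower, 9 of 11 endothelial and erythroid motifs were higher and 1 lower, and 7 of 13 photoreceptor motifs were lower and 0 higher. These counts fell to 5, 4 and 4 with no replicate block. Without TMM 8 horizontal and amacrine motifs were higher and 3 lower, and 5 endothelial and erythroid motifs were higher. Of the 20 GC-rich promoter motifs 6 were higher and 6 lower. In all, 177 motifs were higher and 206 lower, of which 28 and 13 by a log2 fold of at least 0.1.

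The neurogenic cluster was defined by proneural bHLH motifs, the E-box patterns of factors that drive neuron formation. NEUROD1 was higher by a log2 fold of 0.19 ± 0.0067 (SE; edgeR adjusted p = 1.44e-06), NEUROD2 by 0.18 ± 0.0054, Neurog1 by 0.16 ± 0.0098 and Atoh1 by 0.14 ± 0.0039. TAL1::TCF3 (0.15) and MYF6 (0.14), E-box motifs outside the list, moved with them. Of the 12 list members 10 were higher, also when adjusted over the list alone; NEUROG2 (0.025, adjusted p = 0.308) and BHLHE23 (0.0030, adjusted p = 0.81) did not pass. With DESeq2 and in thinned cells 11 were higher, and with no replicate block 7. Identical counts make OLIG1, OLIG2 and OLIG3 (0.095) a single measurement. ZBTB7B (−0.17), E2F1 (−0.15), SRF (−0.12), Nfe2l2 (−0.095), ZBTB7C (−0.088) and PAX1 (−0.086) were lowest. For ZBTB7B and ZBTB7C the mean of the other clusters includes cluster 6, at 0.79 and 0.44, so these 2 values may largely mirror that cluster. Of the 8 progenitor homeodomain motifs 6 were higher and 0 lower, and of the 13 photoreceptor motifs 6 were higher and 3 lower. Only 3 homeodomain motifs and 1 photoreceptor motif were higher with no replicate block. All 20 GC-rich promoter motifs were lower in this cluster (mean −0.029), as were all 4 pigment epithelium motifs (mean −0.025). With no replicate block 12 promoter motifs were lower. The mean of the other clusters includes cluster 6, which was high for both lists (0.17 and 0.12). Promoter motifs stood at −0.00013, −0.084, 0.0019 and −0.055 in clusters 1, 2, 4 and 5. Of the AP-1 motifs 17 of 33 were lower and of the endothelial and erythroid motifs 7 of 11, but 9 and 0 without TMM and 6 and 0 with no replicate block. The cluster had 131 motifs higher and 269 lower; without TMM the split was 163 to 158 and with DESeq2 161 to 214.

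On average over list members, clusters 1, 2 and 5 lay below the mean of the other clusters for ganglion cell motifs (−0.077, −0.056 and −0.049). That mean includes cluster 4, at 0.28, and clusters 3 and 6 stood at 0.0035 and −0.11. For TEAD and NFI motifs clusters 1, 2 and 5 lay above the mean of the others (0.037, 0.042 and 0.060). In cluster 2 all 8 SOX motifs rose, with SOX8 at 0.14 ± 0.0094 (SE; edgeR adjusted p = 2.73e-06) and Sox1, outside the list, at 0.15 ± 0.0052. Of the SOX motifs 3 did with no replicate block. There 7 of 8 progenitor homeodomain motifs rose, LHX2 by 0.099 among them. All 20 GC-rich promoter motifs fell in cluster 2 (mean −0.084 ± 0.00022, SD, n = 2, against 0.068 ± 0.0011 for SOX motifs), as did all 4 pigment epithelium motifs and 11 of 13 horizontal and amacrine motifs. RORB (0.14) and CEBPA (0.14) were also high in cluster 2, and MYBL1 (0.44) most of all. Cluster 2 was low for ZBTB7B (−0.39), HIF1A (−0.21), NEUROD1 (−0.20), ZBTB7C (−0.19), TGIF2 (−0.18) and CUX1 (−0.17). Cluster 1 was highest for MYBL1 (0.34), E2F1 (0.071), CEBPA (0.071), FOXC1 (0.066), IRF2 (0.065) and SOX4 (0.061). It had 4 of 8 E2F motifs called higher and 2 lower, and 0 higher without the replicate block. It was lowest for NEUROD1 (−0.18), CUX1 (−0.17), TGIF2 (−0.16), ATF4 (−0.13), POU4F1 (−0.13) and NEUROD2 (−0.13). Cluster 5, whose cells had a median depth of 1.27 and 1.28 times that of their libraries, was highest for MYBL1 (0.82), E2F1 (0.17) and NR1H4 (0.15) and lowest for ZBTB7B (−0.43), ZBED1 (−0.33) and Dmbx1 (−0.23). E2F1 had 43.6 counts per cell over all kept cells, with log2 folds of 0.11 and 0.22 in the 2 libraries. In cluster 5, 3 of the 8 E2F motifs were higher and 4 lower, and with no replicate block 0 were higher and 3 lower. In it 6 of 7 TEAD and NFI motifs rose and 18 of 20 GC-rich promoter motifs fell. Cluster 6, whose cells had a median depth of 0.594 and 0.662 times that of their libraries, was high for ZBTB7B (0.79), ZBTB7C (0.44) and HIF1A (0.41). All 20 GC-rich promoter motifs rose in cluster 6, as did all 4 pigment epithelium, both CTCF, 11 of 13 horizontal and amacrine, 9 of 12 neurogenic, 12 of 18 microglia and 8 of 13 photoreceptor motifs, with Crx at 0.27 and OTX1 at 0.16. All 8 SOX motifs fell there, and 5 with no replicate block. MYBL1 (−0.52), POU4F2 (−0.18) and Pax6 (−0.18) were lowest there.

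Counts of called motifs were large although most folds were small: cluster 1 had 182 higher and 297 lower, cluster 2 had 222 and 256, cluster 5 had 205 and 224, and cluster 6 had 244 and 186. Without TMM the splits were 229 to 234 in cluster 1 and 200 to 228 in cluster 6. A log2 fold of at least 0.1 was passed by 17, 57, 57 and 169 of these. With no replicate block the calls fell to 96 in cluster 1, 313 in cluster 2, 138 in cluster 3, 201 in cluster 4 and 220 in cluster 5.

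**Figure D3:**
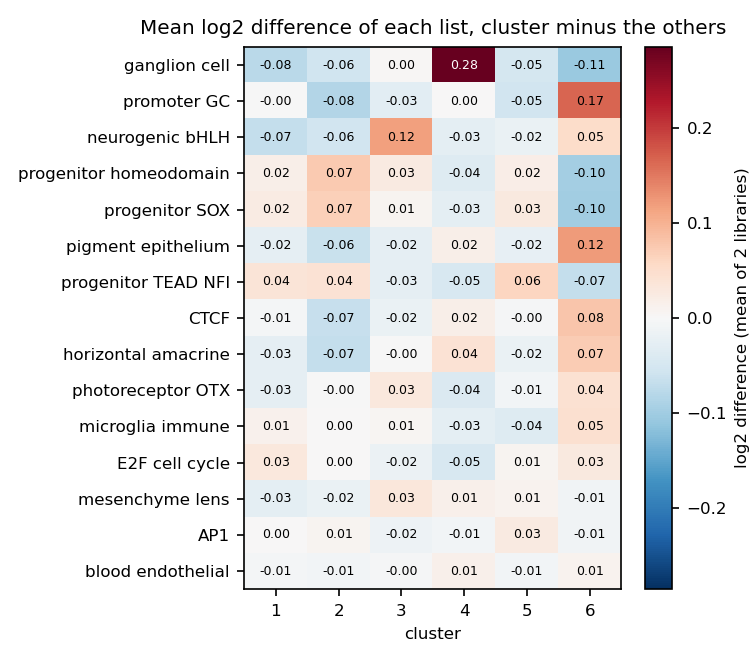
Mean log2 difference of each motif list (rows) between a cluster (columns) and the mean of the other clusters, averaged over 2 libraries, with color and printed value. The ganglion cell list stands at 0.28 in cluster 4, the neurogenic list at 0.12 in cluster 3, and the GC-rich promoter list at 0.17 in cluster 6.

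The held-out measurement asked whether a list differed between clusters built without its own motifs; the peaks of the list still entered through other motifs found in them. Ganglion cell motifs did so by the widest margin of the 15 lists: their mean log2 share differed by 0.31 ± 0.0056 (SD, n = 2) between the highest and the lowest cluster, a 1.24-fold difference. Of 100 random lists of the same size and like mean counts, treated in the same way, 0 reached this difference and the highest stood at 0.11. Random lists lack the near copies that a list of related factors holds. All 5 members were higher in both libraries: POU4F1 by 0.51 ± 0.013, POU4F3 by 0.44 ± 0.013, POU4F2 by 0.37 ± 0.0043, EBF1 by 0.21 ± 0.0064 and ISL2 by 0.041 ± 0.0036. Each differed among the held-out clusters, with edgeR adjusted p from 8.26e-13 to 0.000192, and all 5 also when adjusted over the list alone. Of all 579 motifs 557 passed the same test. Without the replicate block 4 members passed, and ISL2 did not (edgeR adjusted p = 0.535). The high cluster held 14.2% and 13.4% of the cells of replicates 1 and 2. Between the same clusters E2F motifs were lower by a log2 difference of −0.10 ± 0.00050, GC-rich promoter motifs by −0.087 ± 0.013 and TEAD and NFI motifs by −0.056 ± 0.0062. Neurogenic bHLH motifs were higher by 0.055 ± 0.0090, mesenchyme and lens motifs were higher by 0.050 ± 0.0075 and microglia motifs lower by −0.051 ± 0.0042. These values set the high cluster against the lowest alone. Against the mean of the other clusters NEUROD2 stood at −0.029 ± 0.0033 and NEUROD1 at 0.014 ± 0.0080 in the high cluster. At resolution 0.3 the ganglion cell difference was 0.20, and with the cell filter written first it was 0.041.

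Neurogenic bHLH motifs differed by 0.15 ± 0.0093 (SD, n = 2) across clusters built without them and 4 motifs tied to them, a 1.11-fold difference. Of 100 random lists 0 reached it, the highest at 0.082. Higher in both libraries were 11 of 12 members, led by NEUROD1 at 0.29 ± 0.0025, NEUROD2 at 0.26 ± 0.013, Neurog1 at 0.23 ± 0.018, Ascl2 at 0.20 ± 0.0037 and Atoh1 at 0.19 ± 0.0044. BHLHE22 stood at 0.16, the OLIG motifs at 0.12 and NEUROG2 at 0.038 ± 0.026, while BHLHE23 was lower at −0.023 ± 0.011. All 12 passed the edgeR test over clusters, with adjusted p up to 0.00207, and all 12 when adjusted over the list alone. Of all 579 motifs 562 passed the same test. With the replicate block left out 11 members passed, and NEUROG2 did not (edgeR adjusted p = 0.919). In the same clusters ganglion cell motifs were higher by 0.085 ± 0.012, mesenchyme and lens motifs by 0.056 ± 0.0034 and photoreceptor motifs by 0.052 ± 0.0041. GC-rich promoter motifs were lower at −0.061 ± 0.0070, E2F motifs at −0.054 ± 0.0052 and TEAD and NFI motifs at −0.046 ± 0.0017. With the cell filter written first the sign of the list turned, at −0.015.

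Motifs of progenitor factors differed by less. The homeodomain list differed by 0.13 ± 0.0046 (SD, n = 2), with Pax6 at 0.24 ± 0.10, LHX2 at 0.18 and Six3 at −0.062 ± 0.043 (edgeR adjusted p = 0.401). The SOX list differed by 0.12 ± 0.0014, with all 8 members higher, led by SOX8 (0.18), Pou5f1::Sox2 (0.18), SOX15 (0.16) and SOX9 (0.15). The TEAD and NFI list differed by 0.11 ± 0.0044, and 5 of its 7 members were called. TEAD1 (0.18), TEAD4 (0.15), TEAD2 (0.15) and TEAD3 (0.14) led it, and NFIA (0.063, adjusted p = 0.774) and NFIX (0.034, adjusted p = 0.0621) were not called. Without TMM and with DESeq2 both were, with adjusted p of 1.27e-05 and 0.000748 in edgeR without TMM, and Six3 was called with DESeq2. Random lists reached the difference of the homeodomain list in 0, of the SOX list in 1 and of the TEAD and NFI list in 3 of 100 draws. Between the same clusters GC-rich promoter motifs were lower, by −0.19 ± 0.014 for the homeodomain, −0.20 ± 0.015 for the SOX and −0.19 ± 0.027 for the TEAD and NFI contrast. So were pigment epithelium motifs, by −0.13 ± 0.00022, −0.14 ± 0.0049 and −0.12 ± 0.0070. With the promoter list regressed out the differences of these lists were 0.063, 0.066 and 0.094. With no replicate block 5 of the 8 SOX motifs were called. GC-rich promoter motifs differed by 0.20 ± 0.016, with all 20 higher, and 0 of 100 random lists reached this. ZBTB7B (0.89 ± 0.19) and ZBTB7C (0.48 ± 0.093) led them, before ZBTB33 (0.22) and NRF1 (0.20).

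Of lists for other cell classes, the pigment epithelium list (MITF and TFE motifs) differed by 0.11 ± 1.0e-05, and the horizontal and amacrine list by 0.099 ± 0.0079, with TFAP2C at 0.16 and ONECUT1 at 0.12. The photoreceptor list differed by 0.075 ± 0.0023: Crx (0.25 ± 0.0031), OTX1 (0.17), Dmbx1 (0.17) and GSC (0.16) were higher and RORA(var.2) was lower at −0.13 ± 0.028. CTCF motifs differed by 0.10 ± 0.010 and microglia motifs by 0.068 ± 0.010. GC-rich promoter motifs were higher in the same clusters, by 0.098 ± 0.0057 for the pigment epithelium, 0.19 ± 0.018 for the horizontal and amacrine, 0.15 ± 0.025 for the photoreceptor, 0.20 ± 0.021 for the CTCF and 0.18 ± 0.027 for the microglia contrast. In the photoreceptor contrast ganglion cell motifs were lower by −0.36 ± 0.0018, more than the list itself differed. SOX motifs were lower by −0.13 ± 0.0021 in the pigment epithelium, −0.12 ± 0.0075 in the horizontal and amacrine, −0.13 ± 0.0063 in the CTCF and −0.098 ± 0.0033 in the microglia contrast. The high clusters of these lists held 4.76 to 7.08% of a library's cells. With the promoter list regressed out the pigment epithelium difference was 0.039. E2F motifs differed by 0.066 ± 0.0047, with E2F1 at 0.15, and mesenchyme and lens motifs by 0.052 ± 0.0055. In the E2F contrast ganglion cell motifs were lower by −0.30 ± 0.0042. In the mesenchyme and lens contrast 5 of 11 members were higher in both libraries, led by the E-box motifs MSC (0.22), Tcf21 (0.20) and Twist2 (0.19). Another 5 were lower, FOXC1 (−0.050) most of all. Neurogenic bHLH motifs were higher by 0.16 ± 0.014 in the mesenchyme and lens contrast. AP-1 motifs, which also rise with dissociation stress, differed by 0.025 ± 0.011, and endothelial and erythroid motifs by 0.013 ± 0.010, about the size of their spread. For both, the clusters chosen in the 2 libraries were not the same, so their SDs are not the spread of a single contrast. Random lists reached the difference of the horizontal and amacrine and microglia lists in 0 of 100 draws, pigment epithelium in 4, photoreceptor in 10, E2F in 11, CTCF in 21, mesenchyme and lens in 23, AP-1 in 49 and endothelial and erythroid in 96. In total 7 of the 15 lists passed 0.1 in both libraries; with the promoter list regressed out 2 did, and with the cell filter written first 0 did. That filter also turned the sign of the photoreceptor (−0.0077), microglia (−0.0022) and AP-1 (−0.018) differences. Of the 173 members of all lists edgeR called 166 across held-out clusters, where it called 511 to 562 of all 579 motifs.

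**Figure D4:**
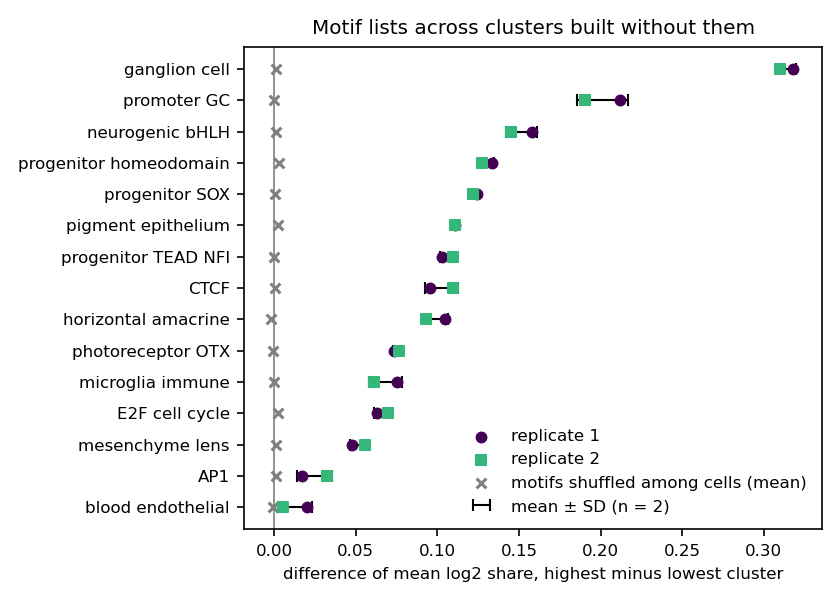
Difference of mean log2 share between the highest and lowest cluster for each motif list (rows), in clusters built without that list. Circles are replicate 1, squares replicate 2, bars the mean ± SD (n = 2) and crosses the mean of 5 shuffles that break all covariation of motifs; the ganglion cell list lies at 0.32 and 0.31.

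Correlations of list scores across cells needed no clusters. Ganglion cell scores fell as E2F scores rose, with r = −0.41 in replicate 1 and −0.34 in replicate 2 (mean −0.377 ± 0.051, SD, n = 2). They ran against TEAD and NFI scores (−0.194 ± 0.027) and with neurogenic scores (0.192 ± 0.00044). They also ran with mesenchyme and lens scores (0.233 ± 0.019) and endothelial and erythroid scores (0.178 ± 0.057), and against GC-rich promoter scores (−0.274 ± 0.0055). With the cell filter written first the neurogenic correlation turned to −0.0047 and the mesenchyme and lens correlation to −0.0078. The E2F correlation fell in size to −0.069, the TEAD and NFI correlation to −0.011, the endothelial and erythroid correlation to 0.026 and the promoter correlation to −0.096. With SOX scores no direction held (0.020 ± 0.029), and with homeodomain scores r was −0.097 ± 0.013. With the promoter list regressed out these became −0.253 for SOX and −0.525 for homeodomain motifs, and with all deposited barcodes the TEAD and homeodomain correlations turned to 0.053 and 0.034, and those with E2F, neurogenic and promoter scores were −0.034, 0.075 and −0.021. SOX and homeodomain scores rose together (0.711 ± 0.0016), and both ran against GC-rich promoter scores (−0.721 ± 0.0096 and −0.778 ± 0.00029). Of 105 pairs of lists 94 had the same sign in both libraries. Cells are not replicates and lists share peaks, so these values have no p.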

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

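The tests in this part were chosen after the barcode totals had been seen. Barcodes left out of the main results, and used only in some alternative settings, held counts in both libraries, well above 0. Of 1828 barcodes found in both, the shallower copy was in replicate 1 for 925 (38.2% of its barcodes, Wilson 95% interval 36.3 to 40.1%) and in replicate 2 for 903 (29.8%, 28.2 to 31.4%). These copies held 0.893% and 1.60% of the counts. A further 576 barcodes of replicate 1 and 1079 of replicate 2 were shallow and found in that library alone, with median totals of 17758 and 14253 motif counts.

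Chance reuse of a barcode by different cells is argued against by the motif profiles. The mean correlation between the copies of a barcode, over the 290 more abundant motifs and copies of at least 20000 counts, was 0.159 for copies in replicate 1 and 0.233 for those in replicate 2, against 5.5e-05 and 0.00037 for other barcodes. The same cells sequenced alike in both libraries are argued against as well, since only 2 shared barcodes passed 300000 counts in both. Counting of reads from the cells of one library in the other is a candidate explanation: log10 totals of shallow and deep copies had r of 0.906 and 0.913, and the deep copy held a median of 127 and 56.1 times the counts. The index reads that would show where such an exchange arose were not used here, and no biological explanation was tested.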

How the results depend on the processing

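The cell filter of 300000 counts and alternatives using at least 1000000 counts, no minimum, leidenalg, a median motif as centre, or clustering without the 6 motifs tracking ZBTB7B were chosen after seeing the data; so were the pairs of correlations printed. The cause was not tested for any change below, but some follow from the settings. All barcodes add shallow copies to the kept cells, and a fold limit or thinning leaves fewer calls by construction. The first filter replaces nearly all kept cells with shallow barcodes. Of the barcodes it keeps, 69.9% in replicate 1 and 63.9% in replicate 2 were the shallower copy of a shared barcode. Agreement of the libraries stayed within 0.01 in r and 1.5 times in the motifs over 0.1 apart. Of the 12 most variable motifs, 8 to 12 stayed in the top 12 (8 with the first filter and 8 without replicate 2). With the cell filter written first the cells formed 2 clusters, neither named; held-out differences were 0.041 for ganglion cell, −0.015 for neurogenic, −0.0077 for photoreceptor, −0.0022 for microglia and −0.018 for AP-1 motifs, and 0 lists passed 0.1. Correlations of ganglion cell scores were then −0.0047 with neurogenic, −0.040 with SOX, −0.051 with homeodomain, −0.011 with TEAD, −0.069 with E2F and −0.0078 with mesenchyme and lens scores. With all barcodes they were 0.075 with neurogenic, 0.072 with SOX, 0.034 with homeodomain, 0.053 with TEAD and −0.034 with E2F scores, and the ganglion cell-like share was 3.44% with no neurogenic cluster; with shallow copies left out and no minimum the shares were 6.28% and 24.2%.

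Resolution 1.0 gave 12 clusters, shares of 9.06% and 5.82% and a ganglion cell difference of 0.30; resolution 0.3 gave a ganglion cell-like share of 28.3%, no neurogenic cluster, and differences of 0.20 and 0.10. Ganglion cell-like and neurogenic shares were 14.6% and 12.8% with 8 components, 14.2% and 14.0% without depth regression, 20.4% and 13.4% with the promoter list regressed out, 15.5% and 13.0% with leidenalg, and 15.7% and 12.8% without the ZBTB7B-tracking motifs. At 1000000 counts the ganglion cell-like share was 14.9%. Leaving out a replicate gave 14.4 to 15.8% and 15.1 to 16.5%, and a SOX correlation of −0.00070 to 0.041.

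The held-out ganglion cell difference was 0.35 with motifs correlated over 0.5 left out, 0.30 with the promoter list regressed out, 0.33 centred on the median motif, 0.32 with leidenalg, 0.30 without the ZBTB7B-tracking motifs, 0.31 at 1000000 counts and 0.33 in thinned cells. The neurogenic difference was 0.14 with motifs correlated over 0.5 left out, 0.14 with the promoter list regressed out, 0.14 with leidenalg and 0.19 in thinned cells. With the promoter list regressed out 2 lists passed 0.1, and correlations of ganglion cell scores were 0.139 with neurogenic, −0.253 with SOX, −0.525 with homeodomain, −0.398 with TEAD and −0.269 with E2F scores; promoter scores then had 0.054 with SOX and 0.038 with homeodomain scores, by construction. Thinned cells gave 0.152, −0.068, −0.202 and −0.274 for neurogenic, SOX, homeodomain and TEAD scores, and 1000000 counts gave 0.141, −0.105, −0.208 and −0.308. Without depth regression the neurogenic correlation was 0.193.

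Called motifs in clusters 1 to 5 numbered 96, 313, 138, 201 and 220 with no replicate block (479, 478, 400, 383 and 429 with it). By construction, leaving the block out puts each motif's shift between the libraries into the residual. A log2 fold of at least 0.1 left 17, 57, 19, 41, 57 and 169 in clusters 1 to 6, and thinning left 297 in cluster 1. Of 54 named motif results, 11 lost their call with no replicate block, 3 with thinning, 2 without the deepest cells and 1 each with DESeq2 and no TMM; none changed sign. The low-count filter left out the motifs of 14 of them, all MYBL1 and E2F1 results among these, and the other 40 kept their call. Without either replicate the tests between clusters had no residual degrees of freedom and were not run; the named motifs had the same sign in both libraries by the rule that chose them. Calls of held-out members, pooled over all lists, numbered 119 with no replicate block to 171 with DESeq2, against 166. With no replicate block they fell from 5 to 4 for ganglion cell and 12 to 11 for neurogenic motifs. They fell from 8 to 4 for E2F, 8 to 5 for SOX and 11 to 5 for mesenchyme and lens motifs. Horizontal and amacrine motifs fell from 13 to 8, microglia motifs from 17 to 11 and AP-1 motifs from 32 to 19. Of 1941 cells, 1721 could be thinned. Motifs with few counts per cell, MYBL1 above all, limit what depth can show. No paired analysis was possible because there is 1 group of libraries; the block is the library shared by all clusters.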

Other observations

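The tests and motif groups in this part were chosen after the data had been seen, except the tests of ZBTB7B by depth and of retina differences, which were written before their results. Groups of motifs noticed in the clusters were held out in the same way as the fixed lists. CUX and ONECUT motifs, 5 in all and known from ganglion and horizontal cell factors, differed by a log2 share of 0.20 ± 0.017 (SD, n = 2) between the highest and lowest cluster. In the cluster highest for held-out ganglion cell motifs, CUX1 stood 0.24 ± 0.011 above the mean of the other clusters and ONECUT1 0.19 ± 0.023, while SCRT2 stood at −0.21 ± 0.0029 and TEAD1 at −0.073 ± 0.0064. Nuclear receptor motifs, 31 in all, differed by 0.11 ± 0.0017, and 30 of them were higher in both libraries. TEAD motifs on their own differed by 0.15 ± 0.0056 and NFI motifs by 0.028 ± 0.0029. The clusters chosen in the 2 libraries were not the same for nuclear receptor and NFI motifs, so those SDs are not the spread of a single contrast. MYBL1, the motif with the fewest counts, differed by 1.62 ± 0.079, and stood at −1.17 ± 0.023 in the cluster highest for ganglion cell motifs. It had 7.53 counts per cell over all kept cells.

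The 6 most variable motifs, ZBTB7B, ZBTB7C, HIF1A, Stat4, GLIS2 and INSM1, varied together: a cell's extra counts of ZBTB7B appeared nearly 1 for 1 in the other 5, with slopes from 0.960 to 1.07 and a lowest correlation of 0.915. This is consistent with a peak, or a few peaks, that hold all 6 motifs. Depth stays open too, and the fall in the CV of ZBTB7B predicted for it beforehand was met. Within the middle of 3 equal classes of cells by depth its excess CV was 0.327 and 0.360 times that over all cells. The ratio was at most 0.373 for any of the 6, and 0.818 and 0.789 for the median motif. Of the cells with more than 3 times the median ZBTB7B share, 16 of 17 in replicate 1 and 16 of 16 in replicate 2 were in the shallowest class. Both may hold at once, and no biological explanation was tested.

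The 68 motifs whose shares differed by more than 0.1 between libraries differed within clusters as well: their median absolute log2 ratio in the least affected cluster was 0.918 times that over all cells, which argues against a different mix of cells as the source. For Lhx8 the cells did not overlap: the highest cell of replicate 1 had 0.140% of its counts in this motif and the lowest of replicate 2 had 0.25%. The 56 motifs that varied with Lhx8 across cells in both libraries had log2 ratios from −0.63 to 0.055, with a median of −0.0019. Since Lhx8 equalled PAX4 in replicate 1, they were chosen there by the counts of PAX4. The 77 motifs that varied with Lhx8 in replicate 2 had a median of −0.0016. These medians argue only against a broad difference between the retinas in the activity of factors at such sites. In replicate 1 Lhx8 had the count of PAX4 in 890 of 890 cells, and in replicate 2 in 0 of 1051, with PAX4 itself at a log2 ratio of −0.029, which is consistent with different sites counted for Lhx8 in the 2 libraries, whether through the peaks or the motif search. Tcf7 (log2 ratio −0.30) likewise equalled TCF7L1 in 890 cells of replicate 1 and in 2 of 1051 of replicate 2; for the other motifs over 0.1 apart such a difference stays open.

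LBX2, GSX1, GSX2 and HOXB3 followed ZBTB7B in replicate 1 (slopes of 0.881, 0.812, 0.842 and 0.820) and not in replicate 2 (−0.098, −0.186, −0.132 and −0.130).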
